A study of Arabidopsis thaliana with 4 samples.

How the data were processed

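Small RNA was sequenced from leaves and roots of 30-day-old Arabidopsis thaliana plants grown in hydroponic medium, with or without 0.3 M mannitol for 3 h. Per the labels' protocols, material from 3 biological replicates was combined before RNA extraction, leaves and roots came from the same plants, RNAs of 18 to 28 nt were cut from a gel, and libraries followed an Illumina small RNA preparation. The 4 groups, control leaf, control root, osmotic leaf and osmotic root, therefore hold 1 library each, and groups were taken from the sample titles.

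The deposited files give, for each distinct sequence, a normalized abundance in RPM, a rate of reads over the library's total. The authors' normalization was read from the values, since each of the 4 columns sums to 1000000 and every value is a whole multiple of the smallest value above 0 in its column. The submitters' processing notes name the genome build TAIR 9. Adapter trimming, the aligner and its mismatch setting are not given in the sources used here. The list holds 5204808 distinct sequences of 19 to 28 nt found in at least 1 of the 4 libraries, with 0 where a sequence was absent.

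Division of each value by the worth of 1 read (0.0687, 0.0748, 0.0836 and 0.0741 RPM in control leaf, control root, osmotic leaf and osmotic root) gave whole reads for 100% of values within a tolerance of 1e-06. The recovered depths were 14549679, 13368383, 11963518 and 13491586 reads in that order. Every sequence was matched without mismatches to both strands of the nuclear, chloroplast and mitochondrial genomes of TAIR10.1, the reference at hand. All coordinates refer to that build. Of the listed sequences 47 matched nowhere, 75.1% matched a single place, and the most repeated matched 7778 places. The list thus holds almost only perfect matches, though the sources used here do not state a filter for them. Reads whose sequencing errors, edited bases or untemplated tails leave no perfect match are nearly absent from all values.

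A sequence that matched several annotation classes was given to the first of chloroplast genome, mitochondrial genome, rRNA, tRNA, snRNA and snoRNA, miRNA, TAS (trans-acting siRNA loci), transposon or pseudogene, protein-coding gene, other annotated and unannotated. The reference annotates the small-subunit genes of the rDNA but not the large-subunit gene, so the 4000 bp after each annotated unit were counted as rRNA. It marks few transposons as such, and most 24-nt siRNA loci therefore fall in the unannotated class.

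MiRNA reads, used for families and for scaling, were those identical to an annotated mature sequence. The miRNA class above is wider and holds reads from anywhere in annotated miRNA genes. Of 428 annotated mature entries with 350 distinct sequences, 1 sequence that also matched a structural RNA or organelle was left out, and the other 349 were summed into 214 families. Reads of multi-mapping sequences in TAS loci were shared equally among their places. Those in tRNA genes were shared equally among the anticodon groups they matched, so groups with common sequences are not independent. For 24-nt siRNAs, reads with a single place were counted in 500-bp windows. Values were scaled to genome-matched reads as RPM. For a pair of libraries the RPM ratio was given with an exact conditional binomial 95% interval, and shares of reads with an exact Clopper-Pearson 95% interval. These intervals cover counting error only, because each group holds 1 library and variation between plants or preparations is unmeasured. Reads amplified by PCR without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error. A family, locus or window counted as higher or lower where it had at least 50 reads in the 2 libraries together, differed at least 2-fold, and had an interval that excluded 1. Against a library with 0 reads a floor of 3 reads was used for a lower bound. Such a rule compares 2 libraries, not the conditions, and gives no p-value.

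Across all 4 libraries, limma was fitted to log2(RPM + 1) of families with at least 50 reads, with tissue and treatment as additive terms, 1 residual degree of freedom and Benjamini-Hochberg adjustment at 0.05. Fold changes of this fit are on the log2(RPM + 1) scale, which understates the change of rare families. The design had reserved edgeR's quasi-likelihood test for files of counts; on the recovered whole reads it was run as an added alternative and called 0 families for osmotic against control and 59 for leaf against root. On simulated counts for osmotic against control, 20 of 78 families were changed in each of 20 runs, with as many up as down. Each change was the same in leaf and root, and a dispersion of 0.02 was assumed. There limma recovered 60.3% of 2-fold and 86.8% of 4-fold changes, with 0.6 and 0.15 false calls per run. The edgeR test recovered 32.5% and 91.8%, with 0.4 and 0.45. In the real libraries most families shifted one way and some differed in sign between leaf and root, so these rates may not carry over. The window rule, tested on simulated data with 200 changed windows, recovered 85.5% of 3-fold changes in leaf and 87.0% in root, and 7.5% and 7.0% of 1.5-fold changes. False calls in those 3-fold tests numbered 41 among 13074 leaf windows and 32 among 13429 root windows.

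Groups, tests, most alternatives, 10 lists of miRNA families and the rule for naming items were fixed before the data were examined. The text names the 6 families with the highest and the 6 with the lowest ratio in each comparison, the 5 with most reads in each library, examples from each list (the largest differences and the most abundant member), all 8 TAS loci, the 5 tRNA anticodon groups with most reads, and the 3 highest and 3 lowest windows per tissue. A list's median was placed among 10000 random lists of the same size matched on mean RPM in 5 bins. Reads from the chloroplast genome were fixed as the mark of leaf material in a root library. Alternatives covered the scaling (miRNA reads, TMM factors from edgeR over families, reads outside rRNA, tRNA and organelle genomes), the read minimum, the fold, length variants with ends within 2 nt, single mature sequences, pseudocounts of 0.5 and 5, window size and multi-mapping reads. Of these, the scaling to reads outside rRNA, tRNA and organelle genomes was added after seeing the data, as were the most abundant arm of each family, edgeR on recovered reads, sense-strand TAS reads and tRNA reads that start at the 5′ end. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, R 4.3.3, limma 3.58.1 and edgeR 4.0.16.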

Results

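Small RNAs of 19 to 28 nt were profiled in Arabidopsis leaves and roots to find those that respond to high osmotic stress, imposed with 0.3 M mannitol, a sugar alcohol that lowers the water potential of the medium, for 3 h. There were 4 libraries, 1 each for control leaf, control root, osmotic leaf and osmotic root, and each was a pool of 3 biological replicates. Depth was 14549679 reads in control leaf, 13368383 in control root, 11963518 in osmotic leaf and 13491586 in osmotic root. None of the differences between libraries has a replicate check, and their intervals cover counting error only.

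Fragments of rRNA took a far larger share of both osmotic libraries. They made up 30.4% of genome-matched reads in control leaf and 45.3% in osmotic leaf, and 25.6% in control root and 47.5% in osmotic root, each with a Clopper-Pearson 95% interval within 0.1 percentage points. MiRNAs are regulators of mRNAs cut from hairpin precursors. Their class, reads from anywhere in annotated miRNA genes, was 17.5% of reads in control leaf against 11.7% in osmotic leaf. It was 11.1% in control root against 7.36% in osmotic root. Reads from unannotated sequence, where most heterochromatic siRNA loci lie, were 19.5% and 13.4% in control and osmotic leaf and 35.8% and 21.7% in control and osmotic root. Reads of tRNA were 5.63% and 7.70% in control and osmotic root and 6.10% and 6.29% in leaf.

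The 24-nt class, mostly siRNAs that guide DNA methylation, was the most abundant length in all 4 libraries. It formed 30.0% (95% interval 29.9 to 30.0) of control leaf reads, 42.3% of control root, 24.7% of osmotic leaf and 30.0% of osmotic root. The 21-nt class, the usual length of miRNAs and trans-acting siRNAs, formed 22.3%, 14.7%, 18.2% and 14.5% of the same libraries. Once rRNA, tRNA and organelle reads were set aside, the 24-nt share was 42.7% in control leaf and 43.0% in osmotic leaf, so the direction of the leaf difference turned, while in root it remained lower at 52.6% against 55.9%. Adenine was the first base of 56.7% and 53.6% of 24-nt reads in control and osmotic leaf and of 61.6% and 57.9% in control and osmotic root. Uracil, read as T, began 59.9% and 50.5% of 21-nt reads in control and osmotic leaf and 54.2% and 40.9% in control and osmotic root. These first bases were counted over all genome-matched reads, rRNA fragments included. Fragments of rRNA were 618048 of 3244153 21-nt reads in control leaf and 640284 of 2173542 in osmotic leaf. In control and osmotic root they were 424536 of 1971787 and 787599 of 1960607. The lower shares of uracil and adenine therefore cannot be assigned to miRNAs or siRNAs. Chloroplast genome reads, the mark of leaf material, were 7.34% in control leaf and 8.69% in osmotic leaf against 0.2002% in control root and 0.207% in osmotic root.

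**Figure D1:**
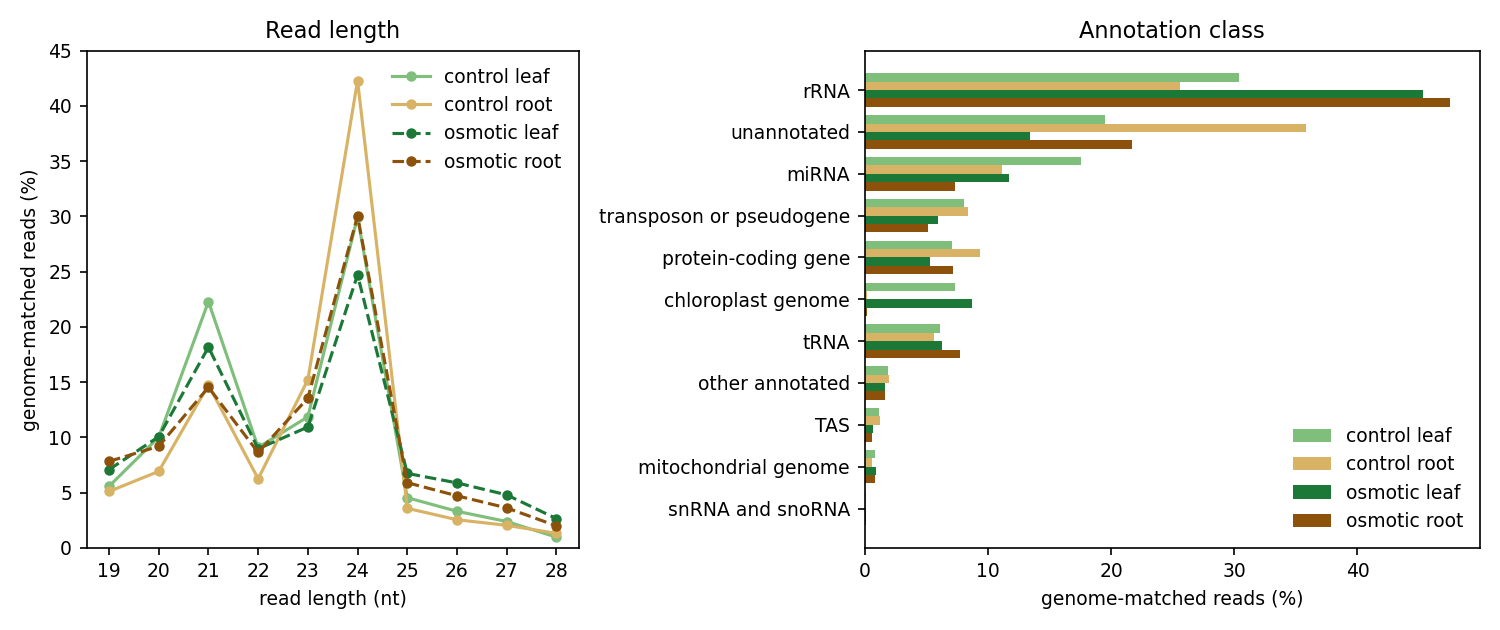
Percent of genome-matched reads by read length in nt (left, 1 line per library) and by annotation class (right, 1 bar per library) in the 4 libraries. The rRNA bars of osmotic leaf (45.3%) and osmotic root (47.5%) exceed those of control leaf (30.4%) and control root (25.6%), and the 24-nt peak is highest in control root (42.3%).

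In leaf, most miRNA families were lower in RPM after mannitol, and miR172 stood out among the abundant ones. MiR172, which targets AP2-type transcription factors of flowering and phase change, was at 1232 RPM in control leaf and 225.5 RPM in osmotic leaf, 5.46-fold lower (log2 ratio -2.45, 95% interval -2.51 to -2.39). Of 63 families tested, 19 were at least 2-fold lower and 0 at least 2-fold higher, and 56 of the 63 lay below 0. The copper-related families miR408 and miR398 were among the few above 0.

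The median leaf family lay at a log2 ratio of -0.78, and this shift depended on the scaling. It was -0.21 relative to miRNA reads, -0.37 with TMM factors and -0.27 relative to reads outside rRNA, tRNA and organelle genomes. The split of higher and lower families was 1 and 4, 0 and 6, and 0 and 6 under those scalings, against 0 and 19 in the main one. Leaf families with a log2 ratio between -0.57 and 0 changed sign under at least 1 of them. The 6 that were lower with TMM factors and with reads outside structural RNAs had the lowest ratios of all, and the first 4 of them were also lower relative to miRNA reads.

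These 6 were miR847, miR839, miR172, miR840, miR852 and miR5996. MiR847, which targets the auxin repressor gene IAA28, fell from 102 reads in control leaf to 14 in osmotic leaf (log2 ratio -2.58, -3.504 to -1.77). MiR839 was rare too, with 54 and 8 reads (log2 ratio -2.47, -3.76 to -1.39), as were miR840 (-1.60) and miR852 (-1.55). MiR5996 was at 61.3 and 21.3 RPM (log2 ratio -1.52, -1.73 to -1.32). Most leaf miR172 reads were the sequence AGAATCTTGATGATGCTGCAT shared by miR172a (chromosome 2, 11942918 to 11942938, minus strand) and miR172b-3p (chromosome 5, 1188211 to 1188231, minus strand), with 15621 reads in control leaf and 1962 in osmotic leaf. The reads of the sequence shared by miR172b-5p and miR172e-5p, from the opposite arm, were 2266 and 728.

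At the other end, miR408, which targets plantacyanin and laccase mRNAs, was highest at 102 RPM in control leaf and 138 RPM in osmotic leaf (log2 ratio 0.43, 0.33 to 0.54), short of 2-fold except relative to miRNA reads. MiR165 (log2 ratio 0.31), which targets HD-ZIP III transcription factors, miR319 (0.23, -0.59 to 1.05, from 28 and 27 reads), miR398 (0.17), miR168 (0.16), which targets AGO1, and miR1888 (0.07, -0.40 to 0.55) came next. Relative to the median family, miR408, miR165, miR398 and miR168 lay 1.21, 1.09, 0.96 and 0.95 log2 units higher. Nearly all miR398 reads were miR398a-5p (chromosome 2, 1040948 to 1040968, plus strand), with 92578 reads in control leaf and 85845 in osmotic leaf, whereas the arm that pairs with its known targets, miR398a-3p, had 144 and 227. For miR408 (chromosome 2, 19319866 to 19319953, plus strand) the 5p arm had 945 and 1137 reads and the 3p arm 543 and 515.

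Among the lists, the copper-related one stood apart. Its 2 measured members in leaf, miR398 and miR408, had a median log2 ratio of 0.30, at percentile 99.0 among 10000 random lists, and neither met the rule. With ends within 2 nt the list's percentile in leaf was 92.6. The auxin list, with 6 measured, held 3 lower (miR847, miR160 and miR167, the last 2 targeting ARF genes) and 3 that met neither side, for a median of -1.01 at percentile 7.84. All 6 lay below the median of all families, and with TMM factors only miR847 was lower. MiR167 was the most abundant of them, at 39807 RPM in control leaf and 19175 RPM in osmotic leaf (log2 ratio -1.05). Of 10 drought, salt, osmotic or ABA families, 3 were lower (miR160 at -1.30, miR167, and miR169 at -1.11, which targets NF-YA genes) and 7 neither, with a median of -0.91 at percentile 27.7. With TMM factors 0 of the 10 were lower.

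The 7 leaf and phase development families included 1 lower, miR172, and had a median of -0.55 at percentile 55.0. Their most abundant member, miR157, was at 41590 RPM in control leaf and 28365 RPM in osmotic leaf (log2 ratio -0.55, positive relative to miRNA reads), and miR156, which like miR157 targets SPL genes, had a ratio of -0.70. Of 23 families listed as specific to Brassicaceae, 9 were lower, among them miR847, miR839, miR173 (-1.24) and miR822 (-1.21), while the abundant miR158 was at -0.41, positive relative to miRNA reads, and the list's median of -0.90 lay at percentile 26.8. The 6 triggers of TAS and other secondary siRNAs held 1 lower, miR173, with miR390 at -0.96 and a median of -0.78 at percentile 54.0. In the remaining lists, small RNA machinery had 0 of 3 lower (miR162 at -0.69, miR168 at 0.16, median -0.51, percentile 73.2), and phosphate had 1 of 2 lower (miR399 at -1.08, miR827 at -0.64, median -0.86, percentile 44.3). The lone sulfate family miR395 (-0.50, percentile 70.8) and the lone MYB-targeting family miR159 (-0.40, percentile 87.6) met neither side, and both turned positive relative to miRNA reads.

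**Figure D2:**
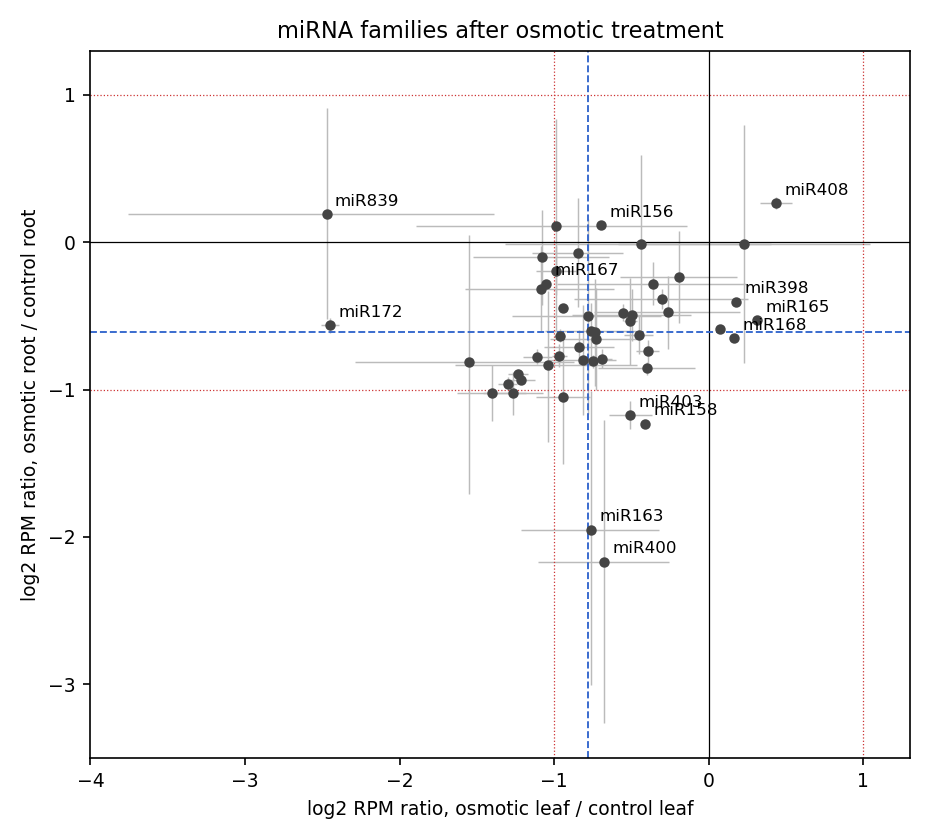
Log2 RPM ratio of each miRNA family tested in both tissues, osmotic against control, in leaf (x axis) and root (y axis), with 95% counting intervals as grey bars, the medians of the leaf and root families as blue dashed lines and 2-fold limits as red dotted lines. Most families lie below 0 on both axes, miR172 (-2.45 in leaf, -0.56 in root) and miR400 (-0.68 and -2.17) lie far from the medians, and miR408 (0.43 and 0.27) is above 0 in both.

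In root, miRNA families were also lower in RPM, but other families led. MiR158, the most abundant of those that met the rule, was at 16274 RPM in control root and 6928 RPM in osmotic root, 2.35-fold lower (log2 ratio -1.23, -1.24 to -1.22). MiR403, which targets AGO2, was at 218 and 96.4 RPM (log2 ratio -1.18, -1.27 to -1.08). MiR397, which targets laccase mRNAs, was highest, at 18.6 RPM in control root and 29.4 RPM in osmotic root (log2 ratio 0.66, 0.43 to 0.90). Of 61 families tested, 9 were at least 2-fold lower, 0 higher, and 55 lay below 0.

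The root median was -0.61, against -0.03 relative to miRNA reads, -0.01 with TMM factors and 0.026 relative to reads outside rRNA, tRNA and organelle genomes. Each of those scalings gave 1 higher and 2 lower families. The 1 higher was miR397 and the 2 lower were miR400 and miR163, so the calls of miR158 and miR403 ended there although both kept their sign. Root families with a ratio between -0.64 and 0 changed sign under at least 1 of the scalings.

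MiR400, which targets pentatricopeptide repeat genes, had 49 reads in control root and 11 in osmotic root (log2 ratio -2.17, -3.26 to -1.21). MiR163, a 24-nt miRNA that targets methyltransferase genes, had 46 and 12 (-1.95, -3.004 to -1.01). MiR846 (-1.44, -1.68 to -1.21) and miR4228 (-1.09, -1.99 to -0.25) completed the lowest 6. Above 0 lay miR397, miR408 (604 and 727 RPM, log2 ratio 0.27, 0.22 to 0.31), miR2111 (0.23, -0.24 to 0.71), miR839 (0.19, -0.52 to 0.91), miR156 (0.12, 0.10 to 0.13) and miR833 (0.11, -0.61 to 0.84). The intervals of miR2111, miR839 and miR833 hold 0, so no difference of these was detectable at this depth. Most reads of miR397 were miR397b (chromosome 4, 7878730 to 7878750, minus strand), with 217 reads in control root and 374 in osmotic root.

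The copper list again had the highest place, with 3 families measured, 0 higher or lower by the rule, and a median of 0.27 at percentile 99.7. Its members were miR397, miR408 and miR398, and the last, which targets the copper and zinc superoxide dismutases CSD1 and CSD2, was at -0.40 and positive under the other scalings. Nearly all its root reads were miR398a-5p (62798 and 47805), while the target-pairing arm miR398a-3p had 309 and 327 (log2 ratio 0.068, -0.16 to 0.30). The Brassicaceae list lay lowest, with 7 of 19 lower, among them miR400, miR163 and miR158, and a median of -0.81 at percentile 0.525. In the drought list 0 of 10 met the rule (miR160 at -0.96, miR168 at -0.65, median -0.69, percentile 31.6), and in the auxin list 0 of 5 (miR160, miR393 at -0.80, miR167 at -0.28, median -0.63, percentile 55.3). Leaf and phase families numbered 7, of which 0 met the rule (miR156 at 0.12, miR166 at -0.59, median -0.48, percentile 88.0). Small RNA machinery had 1 of 3 lower, miR403, with miR168 at -0.65 and a median of -0.79 at percentile 17.9. Secondary siRNA triggers had 1 of 6 lower, miR400, with miR173 at -0.90 and a median of -0.80 at percentile 12.1. For phosphate, miR399 (-0.10) and miR2111 gave a median of 0.07 at percentile 96.2, and miR395 (-0.49, percentile 53.2) and miR159 (-0.74, percentile 46.4) stood alone in the sulfate and MYB lists.

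Over both tissues, miR775 and miR823 were lower in each in RPM, while 0 families were lower in both relative to miRNA reads, with TMM factors or relative to reads outside structural RNAs. Of 50 families tested in both, 13 were lower in leaf and 7 in root, and the 2 shared compare with 1.82 for independent lists of those sizes. The leaf and root comparisons share no library, but their plants were the same, and no difference between the tissue responses was tested. In an additive limma fit over 78 families, 0 were called for osmotic against control at a Benjamini-Hochberg adjusted p of 0.05, 34 had an unadjusted p under 0.05, and miR823, miR775, miR160, miR822, miR173 and miR840 shared the smallest adjusted p of 0.0595. MiR823 had a log2 difference of -1.18 (SE 0.22) and was lower in both tissues. With edgeR on the recovered reads 0 were called too and 12 had an unadjusted p under 0.05. Relative to reads outside rRNA, tRNA and organelle genomes, limma also called 0, and 7 had an unadjusted p under 0.05. The smallest limma adjusted p there was 0.125, and the median log2 difference was -0.15 against -0.56 in the main fit. The count depended on settings, since pseudocounts of 0.5 and 5 gave 34 and 19 lower families. By contrast, median-ratio factors gave 2 higher, miR408 (log2 difference 1.08, SE 0.24, limma adjusted p 0.00151) and miR397 (0.96, SE 0.24, limma adjusted p 0.00457). Limma draws each family's spread toward a common one, weighted by prior degrees of freedom. These were 4.16 in the main fit and 13.0 at a pseudocount of 0.5. They were 138 with median-ratio factors and infinite at a pseudocount of 5, so calls there rest almost wholly on the common spread.

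Leaf and root libraries differed in more families than control and osmotic libraries did. MiR157 was at 41590 RPM in control leaf and 428 RPM in control root, 97.1-fold higher in leaf (log2 ratio 6.602, 6.56 to 6.64), and miR391 at 1200 and 12.1 RPM (6.63, 6.41 to 6.86). On the root side, miR829 was at 832 RPM against 15.3 RPM in leaf (log2 ratio -5.76, -5.96 to -5.57) and miR869 at 295 against 4.74 RPM (-5.96, -6.32 to -5.62). In the control libraries 71 families were tested, of which 25 were higher and 20 lower in leaf. Relative to miRNA reads, which formed a larger part of the leaf library, the split was 14 and 34.

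The most leaf-biased families were miR847, with 102 reads in control leaf and 0 in control root (at least 31.2-fold higher), and miR5996 with 892 and 2 reads (log2 ratio 8.68, 6.82 to 11.73). MiR850 (6.84, 4.34 to 12.16), miR391, miR157 and miR843 (6.41, 5.18 to 8.04) followed. Those most biased to root were miR397 (-6.08, -7.96 to -4.70), miR869, miR829, miR846 (-5.16), miR842 (-4.63) and miR837 (-3.90). MiR842 (22577194 to 22577214) and miR846-5p (22577426 to 22577446) lie side by side on the plus strand of chromosome 1. MiR829-3p.1, of sequence AGCTCTGATACCAAATGATGGAAT (chromosome 1, 11834094 to 11834117, minus strand), supplied most reads of its family.

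In the osmotic libraries 61 families were tested, with 16 higher and 23 lower in leaf, and 12 and 32 relative to miRNA reads. MiR825 had 110 reads in osmotic leaf and 0 in osmotic root (at least 41.4-fold higher), and miR5996 (6.58), miR843 (6.57), miR157 (6.53), miR391 (6.50) and miR850 (5.95) followed. MiR869 (-5.88), miR397 (-5.46), miR829 (-5.31), miR846 (-4.53), miR842 (-4.35) and miR837 (-3.98) were lowest. Members of miR172 also split by tissue, the shared sequence of miR172c and miR172d-3p having 1850 reads in control root and 19 in control leaf.

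In the additive limma fit, 57 of the 78 families differed between leaf and root, 28 higher and 29 lower in leaf. MiR157 (log2 difference 6.56, SE 0.20) and miR391 (6.42, SE 0.21) had the smallest limma adjusted p of 1.82e-05, both higher in leaf in 2 of 2 pairs. MiR869 (-5.62, SE 0.21) and miR829 (-5.43, SE 0.23) led on the root side. The spread in this fit rests on 1 residual degree of freedom shared over families.

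**Figure D3:**
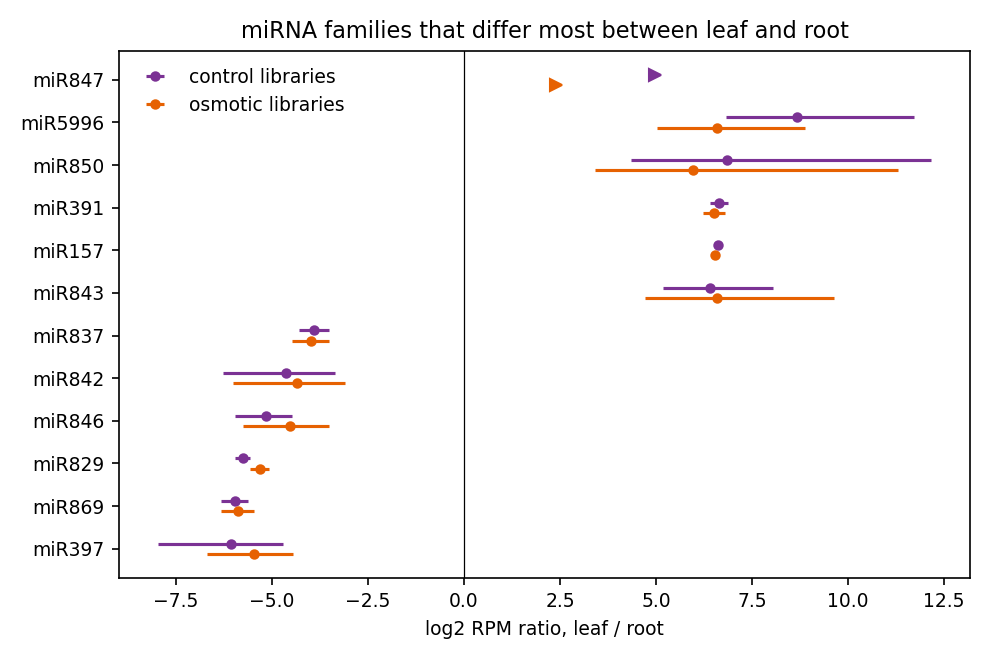
Log2 RPM ratio of leaf against root for the 6 families most biased to each tissue in the control libraries, in control (purple) and osmotic (orange) libraries, with bars for 95% counting intervals and right-pointing triangles for lower bounds where root had 0 reads. Families lie on the same side in both pairs, from miR397 (-6.08 in control) to miR5996 (8.68 in control).

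In control leaf the most abundant families were miR157 (28.2% of reads in miRNA families), miR167 (27.0%), miR156 (14.3%), miR158 (8.36%) and miR166 (6.47%). In osmotic leaf miR157 (28.7%), miR167 (19.4%), miR156 (13.1%), miR166 (10.14%) and miR158 (9.36%) led. Control root was led by miR166 (26.3%), which like miR165 targets HD-ZIP III genes, miR158 (19.2%), miR167 (10.5%), miR168 (8.41%) and miR156 (8.33%). Osmotic root had miR166 at 26.1%, miR156 at 13.5%, miR167 at 12.9%, miR158 at 12.2% and miR168 at 8.01%.

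Trans-acting siRNAs, made in phase from TAS transcripts after a miRNA cuts them, were lower in both osmotic libraries. All 8 TAS loci together gave 11587 RPM in control leaf and 7050 RPM in osmotic leaf (log2 ratio -0.72, -0.73 to -0.70), and 12108 RPM in control root and 5826 RPM in osmotic root, 2.08-fold lower (-1.06, -1.07 to -1.04). In root TAS1a (chromosome 2, 11721539 to 11722468, minus strand) was at -1.28 and TAS3b at -1.27, and in leaf TAS2 (chromosome 2, 16539384 to 16540417, minus strand) was at -1.08, and these met the 2-fold rule. With reads outside structural RNAs as the base the sums were at -0.20 in leaf and -0.42 in root, and no locus met it.

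The other TAS1, TAS2 and TAS3 loci with many reads were lower without reaching 2-fold. TAS1b was at -0.64 in leaf and -0.78 in root, TAS1c at -0.87 and -0.99, and TAS3a (chromosome 3, 5861491 to 5862437, plus strand) at -0.88 and -0.85, while TAS2 was at -0.98 in root. TAS1a (-0.37) and TAS3b (-0.53) in leaf changed sign relative to miRNA reads. TAS4 (chromosome 3, 9417551 to 9418705, minus strand), whose siRNAs target MYB genes of anthocyanin synthesis, went the other way at 127 RPM in control leaf and 161.24 RPM in osmotic leaf (0.34, 0.25 to 0.44), but its sense-strand reads alone were lower, with 573.5 and 385 reads (-0.29, -0.48 to -0.11). In root TAS4 was nearly absent, at 0.224 and 0.741 RPM (1.72, -0.23 to 4.22), so that control leaf exceeded control root by 9.14 on the log2 scale (7.60 to 11.42). TAS3c had 0.756 RPM in control leaf and 1.003 RPM in osmotic leaf (0.41, -0.90 to 1.73), and 0 reads in control root.

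**Figure D4:**
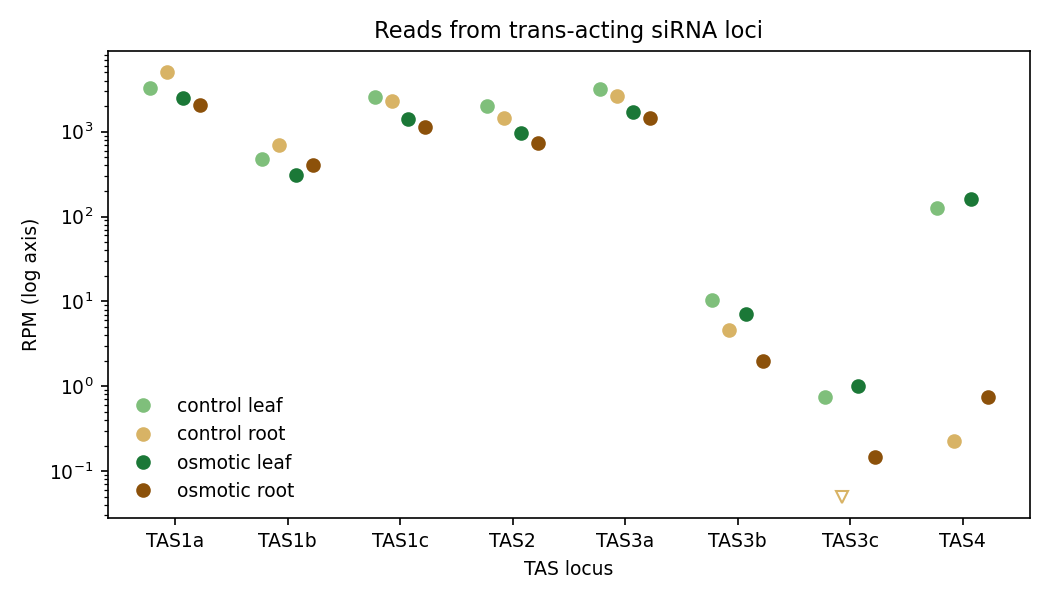
RPM on a log axis at each of the 8 TAS loci in the 4 libraries, 1 point per library, where the open triangle marks 0 reads (TAS3c in control root). TAS1a goes from 5056 to 2082 RPM in root, and TAS4 is at 127 and 161.24 RPM in control and osmotic leaf but below 1 RPM in both root libraries.

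Fragments of tRNA were more abundant in osmotic root and level in leaf. Nuclear tRNA genes gave 56580 RPM in control root and 77343 RPM in osmotic root (log2 ratio 0.45, 0.447 to 0.455), and 61325 and 62653 RPM in control and osmotic leaf (0.03, 0.026 to 0.035). In root, Ala-AGC and Val-CAC were at 0.63, Ala-TGC at 0.49, Ala-CGC at 0.36 and Gly-TCC at 0.17. In leaf the same groups were at 0.01, 0.18, -0.08, 0.31 and 0.11, and with reads outside structural RNAs as the base Ala-TGC was positive there as well. Between 97.2% and 97.9% of tRNA reads in each library began at the mature 5′ end. Reads with the untemplated 3′ end of mature tRNAs have no perfect match and are nearly absent, so this share was in part set by the matching. The 19-nt fragments of Gly-TCC were a mark of root, at 8995 and 7527 RPM in control and osmotic root against 1765 and 1523 RPM in leaf, so this length was lower in the osmotic libraries in RPM where all lengths of Gly-TCC together were higher.

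Loci of 24-nt siRNAs were lower nearly throughout the genome in RPM, in root more than in leaf. In leaf, of 12950 windows of 500 bp, 1451 were at least 2-fold lower and 11 higher, with a median log2 ratio of -0.51. In root, of 13410 windows, 2888 were lower and 17 higher, with a median of -0.77. Relative to uniquely placed 24-nt reads the counts of higher and lower windows were 112 and 209 in leaf and 65 and 94 in root, with medians of -0.02 and -0.05.

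The highest leaf window lay in the gene AT4G11030 (chromosome 4, 6740501 to 6741000), with 3 reads in control leaf and 90 in osmotic leaf (log2 ratio 5.19, 3.60 to 7.49), and sense reads of all lengths from this gene were 4 and 109. It was followed by intergenic windows beside AT4G16520 (chromosome 4, 9309001 to 9309500, 41 and 233 reads, 2.79) and AT1G02950 (chromosome 1, 664501 to 665000, 18 and 79 reads, 2.42). The lowest leaf windows had 0 reads in osmotic leaf. They were intergenic windows on chromosome 5 (2656001 to 2656500, 11.9 RPM in control leaf, at least 47.4-fold lower), chromosome 1 (6594001 to 6594500, 82 control reads, at least 22.5-fold lower, but 0 and 13 reads in control and osmotic root) and chromosome 1 (10144501 to 10145000, 55 control reads, at least 15.1-fold lower).

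In root the window at 2656001 on chromosome 5, 131 bp from AT5G08250, was instead the highest, with 0 reads in control root and 71 in osmotic root (at least 23.5-fold higher). Next were windows in COR47, a dehydrin gene induced by cold and dehydration (chromosome 1, 7085001 to 7085500, 5 and 57 reads, log2 ratio 3.50, 2.19 to 5.17, with 131 and 819 sense reads of all lengths in the gene), and in JAL34 and JR1, jacalin-related lectin genes (chromosome 3, 5595001 to 5595500, 7 and 54 reads, 2.93, 1.79 to 4.32). Lowest were windows in HIPP25 (chromosome 4, 16686501 to 16687000, 84 and 3 reads, -4.82, -7.13 to -3.22), in AT3G02960 (chromosome 3, 667001 to 667500, 47 and 7 reads, -2.76) and between genes on chromosome 1 (9202501 to 9203000, 98 and 15 reads, -2.72).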

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

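In 5 miRNA families and 1 tRNA group the osmotic library lay on one side of its control in leaf and on the other side in root, with both counting intervals away from 0. With 1 library per group none of these differences between the tissues was tested.

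MiR156, which targets SPL genes, had a log2 ratio of -0.70 in leaf and 0.12 in root, a leaf minus root difference of -0.81. The other 4 families went the other way. MiR165 was at 0.31 and -0.53, a difference of 0.84, and miR166, which also targets HD-ZIP III genes, at 0.073 and -0.59, a difference of 0.66. MiR168, which targets AGO1, was at 0.16 and -0.65, a difference of 0.81. MiR398 was at 0.17 and -0.40, a difference of 0.58. Fragments of tRNA Ala-TGC were at -0.081 in leaf and 0.49 in root, a difference of -0.57.

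The signs rest in part on the scaling. With TMM factors over families, miR165 (0.72 and 0.07), miR166 (0.48 and 0.01) and miR398 (0.58 and 0.20) were positive in both tissues, while miR156 (-0.29 and 0.72) and miR168 (0.57 and -0.05) still had opposite signs. Ala-TGC turned positive in leaf relative to miRNA reads (0.49) and relative to reads outside rRNA, tRNA and organelle genomes (0.43).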

How the results depend on the processing

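The counts, shares and ratios named here were recomputed with 1 choice changed at a time, except that edgeR changed the model, the input and the scaling together, while first bases were not recomputed. The scaling to reads outside rRNA, tRNA and organelle genomes, the use of the most abundant arm and edgeR on recovered reads were chosen after seeing the data, as were the size share without those reads, TAS reads of the sense strand only and tRNA reads that start at the 5′ end, and the other settings before. For the main counts, shares and sums, 103 recomputed values kept to the main one, 108 moved, by more than 1.5 times for a count or out of the counting interval of the main value for a share or ratio, and 1 reversed. For single families, loci, tRNA groups and the other read classes 453 kept to it, 129 moved, 55 were no longer past the 2-fold rule, 11 newly passed it and 9 reversed. Where a read minimum, a fold limit or single sequences changed a count, the number of items able to pass changed by construction, and where a scaling did, every ratio of a comparison moved by the same factor. For the other changes the cause was not tested. For osmotic against control within a tissue, no paired analysis was possible because each group holds 1 library, and leaf was paired with root by treatment in the additive fit. DESeq2 was not run, since median-ratio factors in limma stood for that alternative.

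In leaf, osmotic against control, the main counts of 0 higher and 19 lower families became 1 and 4 relative to miRNA reads. They became 6 lower with TMM factors, 11 lower at a minimum of 200 reads, 41 lower at 1.5-fold and 41 lower for single mature sequences. Relative to reads outside structural RNAs and organelles 6 were lower, and with ends within 2 nt 1 was higher, miR8175 (116 and 751 RPM). Reads with shifted ends were not screened for matches to structural RNAs, as the mature sequences were. In root, 0 higher and 9 lower became 1 and 2 relative to miRNA reads, 1 and 2 with TMM factors, 1 and 2 relative to reads outside structural RNAs and organelles, 1 and 32 at 1.5-fold, 14 lower at a minimum of 10 reads and with no minimum, 5 lower at a minimum of 200, and 21 lower for single sequences. Families lower in both tissues, 2 in the main counts, numbered 0 relative to miRNA reads, 0 with TMM factors, 0 relative to reads outside structural RNAs and organelles, 19 at 1.5-fold and 5 for single sequences.

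Between control leaf and control root, 25 higher and 20 lower became 14 and 34 relative to miRNA reads, 44 and 39 for single sequences, 15 higher at a minimum of 200 and 32 lower with no minimum. Between the osmotic libraries, 16 higher and 23 lower became 28 and 40 for single sequences, 9 higher at a minimum of 200 and 26 higher with no minimum. The limma count for osmotic against control, 0 in the main setting, was 2 with median-ratio factors, 14 with ends within 2 nt, 34 with a pseudocount of 0.5 and 19 with a pseudocount of 5, and 0 with no minimum, single sequences, the added scaling and edgeR. The leaf against root count, 57, ranged from 46 with a pseudocount of 5 to 81 for single sequences. Limma's prior degrees of freedom differed between these fits too, from 2.70 for single sequences to infinite in others. They were infinite with ends within 2 nt, a pseudocount of 5 and the added scaling.

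The 24-nt share in control leaf, control root, osmotic leaf and osmotic root was 50.3%, 58.5%, 48.7% and 54.8% among reads with 1 place, 49.8%, 51.5%, 49.7% and 46.7% of distinct sequences, and 42.7%, 55.9%, 43.0% and 52.6% without rRNA, tRNA and organelle reads. The 21-nt share in the same order was 16.7%, 11.6%, 16.1% and 11.8%, then 8.29%, 8.04%, 7.97% and 8.56%, and 28.999%, 15.7%, 27.8% and 16.6%. For rRNA the share was 1.02%, 0.780%, 2.70% and 2.43% among reads with 1 place, since rDNA is repeated, and 2.14%, 2.17%, 3.17% and 2.95% of distinct sequences. For the miRNA class it was 14.6%, 11.8%, 14.3% and 10.2% with 1 place and 0.366%, 0.471%, 0.375% and 0.466% of distinct sequences.

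The log2 ratio of all 8 TAS loci in leaf was -0.67 for 21-nt reads, -0.14 relative to miRNA reads and -0.20 relative to reads outside structural RNAs and organelles, and in root -0.48 and -0.42 under the last 2. For the sense strand only it was -0.51 in leaf and -1.12 in root, and TAS4 in leaf reversed to -0.29. In leaf TAS1a reversed to 0.20 and 0.14 under those scalings and TAS3b to 0.044 relative to miRNA reads. The log2 ratio of nuclear tRNA reads in leaf reversed to -0.040 for 19-nt reads and was 0.60 relative to miRNA reads and 0.54 under the added scaling, and in root it was 0.16, 1.03 and 1.09. For tRNA reads that start at the 5′ end it was 0.021 in leaf and 0.447 in root. Gly-TCC reversed for 19-nt reads to -0.21 in leaf and -0.26 in root, and Ala-TGC in leaf reversed to 0.45 for 19-nt reads, 0.49 relative to miRNA reads and 0.43 under the added scaling.

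Windows of 24-nt siRNAs in leaf, 11 higher and 1451 lower in the main counts, became 112 and 209 relative to unique 24-nt reads, 119 and 198 under the added scaling, 4 and 244 at a minimum of 200 reads and 23 higher with multi-mapping reads shared. In root, 17 and 2888 became 65 and 94, 51 and 150, 4 and 641, and 34 higher, and 26 higher in 1000-bp windows. Depth limits rare families most, since 50 reads in 2 libraries leave an interval of about 2-fold either side for ratios such as that of miR170.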

Other observations

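The libraries also held short sense reads of protein-coding genes, given above only for 2 genes with 24-nt windows. For uniquely placed sense reads of genes with at least 20 reads in the 2 libraries, genes of dehydration and abscisic acid responses stood out in both tissues. Of 32 such genes listed, 25 were measured in leaf, and 21 were at least 2-fold higher and 0 lower in osmotic leaf. Their median log2 ratio was 1.54 against -0.28 for all 6267 protein-coding genes measured, of which 491 were higher and 732 lower. In root 24 were measured, 21 higher and 1 lower (RD20), with a median of 2.69 against 0.56 for 6142 genes, of which 1784 were higher and 310 lower. RD29A had 144 reads in control leaf and 577 in osmotic leaf (log2 ratio 2.28, 95% interval 2.02 to 2.56) and 8 and 383 in root (5.57, 4.57 to 6.79). RAB18 had 11 and 110 in leaf but 0 and 2 in root, below the minimum. HAI1 had 1 and 49 in root (5.601, 3.06 to 10.93), and KIN2 0 and 115 in root, at least 38.0-fold higher. RD29B met the rule in neither tissue, with 26 and 33 reads in leaf (0.63, -0.16 to 1.43) and 13 and 12 in root. RD22 (4 and 4) and COR15A (0 and 1) were not measured in root. A gene with few control reads could pass the minimum only if it was higher in the osmotic library, which can raise the counts of higher genes. Values of 9 of the 32, RD29A among them, had been seen before the list was written.

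Photosynthesis genes went the other way in leaf, where 0 of 24 were higher and 10 lower, with a median of -0.77 at percentile 0.08 among random lists. Relative to reads outside rRNA, tRNA and organelle genomes, a scaling added after seeing the data, only 1 was lower, with a median of -0.26 against 0.23 for all genes. Under it 24 of the 25 dehydration genes were higher, and among all 6267 genes 1018 were higher and 185 lower. In root that scaling gave 22 higher and 0 lower dehydration genes, so the call of RD20 ended, and 3292 higher and 33 lower among all genes. RCA had 2368 and 803 reads (log2 ratio -1.28, -1.40 to -1.16), RBCS1A 2485 and 923 (-1.15) and GAPB 311 and 97 (-1.40). Among all genes with at least 50 reads, chosen for their values, the camalexin genes CYP71A13 (3 and 95 reads, 5.27, 3.68 to 7.57) and PAD3 (3 and 88, 5.16, 3.56 to 7.46) were highest in leaf, and in root PAD3 had 3 and 141 but CYP71A13 only 0 and 2. The jasmonate-responsive genes VSP1 (10 and 100 in leaf) and TAT3 (1 and 83 in root) and the beta-glucosidase gene BGLU24 (2 and 387 in root, 7.58, 5.72 to 10.63) were also among the highest. Among the lowest in leaf were the expansin gene EXPA8 (58 and 2 reads, -4.58, -7.66 to -2.66), the receptor kinase gene BAM2 (61 and 1) and AT3G44570 (chromosome 3, 16158405 to 16159835), whose reads of both strands were 2155 and 52, 34.1-fold lower, but 92 and 139 in root. In control leaf 24.2% of these AT3G44570 reads were 21 nt long.

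The tests below were chosen after the results they bear on were seen, apart from that on copper enzymes, whose values had not been looked at. For the dehydration genes, members whose values had not been seen before listing were compared with random lists of protein-coding genes. The median of 16 such genes in leaf (1.86) and 17 in root (2.67) lay at percentile 100 among 10000 random lists matched on abundance in each tissue, where the highest random medians were 0.73 and 1.76. The list thus lay above other protein-coding genes of like abundance. These sense reads were of all lengths, however. Reads of 24 nt, mostly siRNAs, were 47.8% and 45.7% of the protein-coding class in control and osmotic leaf. In control and osmotic root they were 58.9% and 48.7%. Random lists can therefore hold siRNA loci, so the test cannot decide whether fragments of all mRNAs rose. It remains a hypothesis that reads of the dehydration genes may follow mRNA levels, since the libraries hold no separate measure of mRNA. A change in how fast mRNAs of these genes are broken down was not tested.

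Most miRNA families were lower in RPM in both osmotic libraries, and a larger share of rRNA fragments could account for it. With reads outside rRNA, tRNA and organelle genomes as the base, the median log2 ratio of 61 root families was 0.026 (bootstrap 95% interval -0.13 to 0.16), as that explanation needs. That of 63 leaf families was -0.27 (-0.45 to -0.16), so in leaf it leaves a part of the median family's shift unexplained. The bootstrap resampled families within 1 pair of libraries, so it does not measure whether the shift would recur. Reads in miRNA families were 2142914 of 8053176 such reads in control leaf and 1183690 of 4640334 in osmotic leaf. Their sum thus moved less than the median family. A breakdown that raised fragments of all RNAs alike is argued against, because reads of 25 to 28 nt from protein-coding genes were at 0.15 (0.14 to 0.16) in leaf and 0.67 (0.65 to 0.68) in root against 1.01 and 0.94 for rRNA. Chloroplast reads of those lengths in leaf (0.59) and mitochondrial reads in leaf (0.86) and root (0.62) also lay below rRNA. Over all lengths, 67.0% and 57.5% of mitochondrial reads in control and osmotic leaf also matched the nuclear genome. In control and osmotic root 44.1% and 28.7% did, so the mitochondrial ratios are not of organelle RNA alone. The class of other annotated RNAs lay above rRNA in leaf (1.503) and level with it in root (0.93), so a breakdown of some RNAs stays open. A loss of rRNA alone, a difference in gel cuts and an effect of the treatment on miRNAs stay open and untested.

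Among the lists, the copper-related one had the highest median in both tissues, although its member miR398, nearly all reads of the 5p arm, was below 0 in root, where miR398a-3p was at 0.068 (-0.16 to 0.30). Leaving out reads with shifted ends is argued against as the whole source in root, where the list stayed at percentile 99.6 with ends within 2 nt (median log2 ratio 0.10). Its distance from the median family went from 0.88 (bootstrap 95% interval 0.76 to 1.04) to 0.68 (0.59 to 0.76). Families above the list's median went from 1 of 61 to 6 of 73, and miR398 lay at -0.58, level with the median family. Bootstrap intervals of these distances, also in leaf, resample all families and hold the list's median fixed. They leave out the spread of its few members. In leaf the distance was 1.09 (0.98 to 1.27) without and 1.11 (0.98 to 1.29) with those reads, but the percentile went from 99.0 to 92.6 as tested families went from 63 to 77, so for this list of 2 families the test does not decide. A response like that to copper deficiency, in which FSD1 mRNA goes up and CSD1 and CSD2 mRNAs go down, cannot be told apart from none by these reads, since the log2 ratio of FSD1 minus that of CSD1 and CSD2 was 0.049 (-1.21 to 1.31) in leaf and 0.21 (-1.42 to 1.83) in root. A treatment effect on copper stays among the open explanations.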
